A study of Enterococcus durans with 12 samples.

How the data were processed

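RNA sequencing was carried out on the lactic acid bacterium Enterococcus durans strain A8-1, grown aerobically at 37 °C in MRS broth, a rich medium for lactic acid bacteria, with or without 60 µg/ml sodium selenite. Cells were collected at 14 h and 22 h. The labels name 3 biological replicates for each of the 4 groups, 12 libraries in all. Per the labels' protocols, 3 µg of total RNA per sample entered the NEBNext Ultra RNA library kit. That kit does not mark strand, so reads from a gene and an antisense partner cannot be told apart. Ribosomal RNA genes took almost no counts, and no depletion step is given in the sources used here.

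The authors deposited whole-number counts per gene, with 1 column per library and no normalization. The deposited tables list 2924 genes of 1 sequence, of which 483 carry a gene symbol. All others are named here by their locus tag. Gene coordinates are those of the deposited tables. The genome build, aligner, counting tool, strand setting and treatment of reads that map to several places are not given in the sources used here, so counts of near-identical or overlapping genes are uncertain. Per the submitters' processing notes, the authors tested pairs of groups with DESeq 1.18.0. Every value below was computed from the deposited counts.

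Totals ran from 2834166 to 3168382 counts per library. A count of 0 in a library allowed a level of up to 0.947 to 1.06 CPM (counts scaled to a library of 1e6), taken as 3 counts of its total, and covers counting error only. No pair of replicates agreed within sampling noise: chi-square per degree of freedom ran from 2.86 to 23.8 over the 12 replicate pairs, so each library counted once.

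Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter on low counts and robust dispersions. Selenite was compared with control at each time, and 22 h with 14 h within each medium, in fits that held only the 6 libraries compared. The change of the selenite response between the times was an interaction contrast over all 12 libraries. P-values were adjusted by the Benjamini-Hochberg method, and genes with adjusted p under 0.05 are called risen or fallen. Errors of log2 fold changes are approximate standard errors, from the fold change and the quasi-likelihood F. CPM values are means ± SD over 3 libraries on the TMM scale of the comparison in which they stand, so a group's CPM differs between comparisons.

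Gene lists were fixed from symbols and product names: 20 functional lists, and ribosomal RNA genes as a share of counts only. One list, selenium and molybdenum cofactor genes, had no member among the listed genes, which leaves 19 lists with at least 5 measured members. They were aminoacyl-tRNA synthetases; arginine deiminase, amines and citrate; ATP synthase; candidate selenite reductases; cell wall; chaperones and proteases; and cysteine, methionine and sulfur. DNA repair and SOS, fatty acid and phospholipid, glycerol, glycolysis and pyruvate, metal and metalloid homeostasis, and oligopeptide and amino acid uptake were the next. The last were phosphate uptake, phosphotransferase sugar uptake, prophage and transposon, purine and pyrimidine synthesis, ribosomal proteins, and thiol and peroxide defence. The matching missed the holo-ACP synthase gene LIU_RS00340 and the Spx family gene LIU_RS13075, which stand outside the fatty acid and thiol lists. Lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 19 lists of a comparison.

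The genes named in the text followed a rule. In each selenite comparison they were the 8 largest rises and 8 largest falls among genes with adjusted p under 0.05, all 3 libraries of one group above all 3 of the other, and at least 10 CPM in the higher group. Up to 2 members of each list with the smallest adjusted p joined them. In each time comparison and the interaction the 5 largest each way were taken. For the interaction, the condition on separate libraries was applied, after the data were seen, to the ranges of the selenite minus control differences at the 2 times. Always named were trxA, trxB, gor, groL, dnaK, arcA, the superoxide dismutase gene LIU_RS05585 and the L-lactate dehydrogenase genes LIU_RS02290 and LIU_RS08060. No gene carried the symbol selD. Genes with only a hypothetical product were skipped: 4 rises and 4 falls at 14 h, 2 and 4 at 22 h, 3 falls over time in each medium and 2 falls in the interaction. Other members of a list that are named as examples were chosen after their values were seen.

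The scripts were tested on simulated counts with 200 genes changed by known amounts. At 14 h, 65.7% of genes changed 1.5-fold were recovered, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold. For the interaction these shares were 38.8%, 73.1% and 93.9%, and the share of false calls averaged 4.35% over 10 simulations. That share was 5.05% ± 2.03 at 14 h and 5.69% ± 2.19 at 22 h (SD over simulations), 4.57% over time in control and 4.01% over time with selenite. The simulated counts were drawn independently for each gene from a shared profile. They hold neither the correlation between genes nor the differences with abundance between real libraries, so these shares do not give the error rate in the real data.

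The groups, tests, gene lists and the following alternatives were set before the data were examined: median-ratio size factors, total-count scaling, DESeq2 1.42.0, no count filter, a stricter threshold (adjusted p under 0.005 and a log2 fold change of at least 1), a replicate block, all 12 libraries in one fit, each replicate left out, and an estimated correlation. Added afterwards were the overlap of the 2 selenite responses under other scalings, loess offsets that remove the trend with abundance, subtraction of an even background at the 5th or 1st percentile of counts per kb, genes of at least 64 CPM alone, and 2 fits that left out control libraries. Each replicate was also left out in turn for the gene lists. Samples shared only a replicate number, and whether equal numbers pair the samples is not known, so the main tests used no pairing. Tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.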

Results

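Transcripts of Enterococcus durans A8-1 were counted in broth cultures with or without 60 µg/ml sodium selenite, a soluble selenium salt that is toxic to many bacteria at high levels. Cultures were sampled at 14 h and 22 h, with 3 biological replicates in each of the 4 groups. Totals were 2834166 to 3168382 counts per library. Of 2924 listed genes, 453 had a count of 0 in all 12 libraries.

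Culture time separated the libraries most. The first principal component held 72.7% of the variance over 2282 genes and parted all 14 h libraries from all 22 h libraries, and the second held 11.2%. The most abundant stable RNA, ssrA (transfer-messenger RNA, which frees stalled ribosomes), took 17.0% ± 0.522 of the counts in control at 14 h and 11.3% ± 0.945 with selenite (SD, n = 3). At 22 h its share was 8.25% ± 0.0917 in control and 6.81% ± 0.369 with selenite. The weakest tested genes also differed between libraries. The 5th percentile of CPM per kb over 2088 genes was 10.5 and 10.9 in replicates 2 and 3 of control at 14 h, 5.14 in replicate 1, and 3.32 to 4.22 with selenite at 14 h. At 22 h it was 1.91 to 3.93 in control and 2.61 to 5.90 with selenite.

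**Figure D1:**
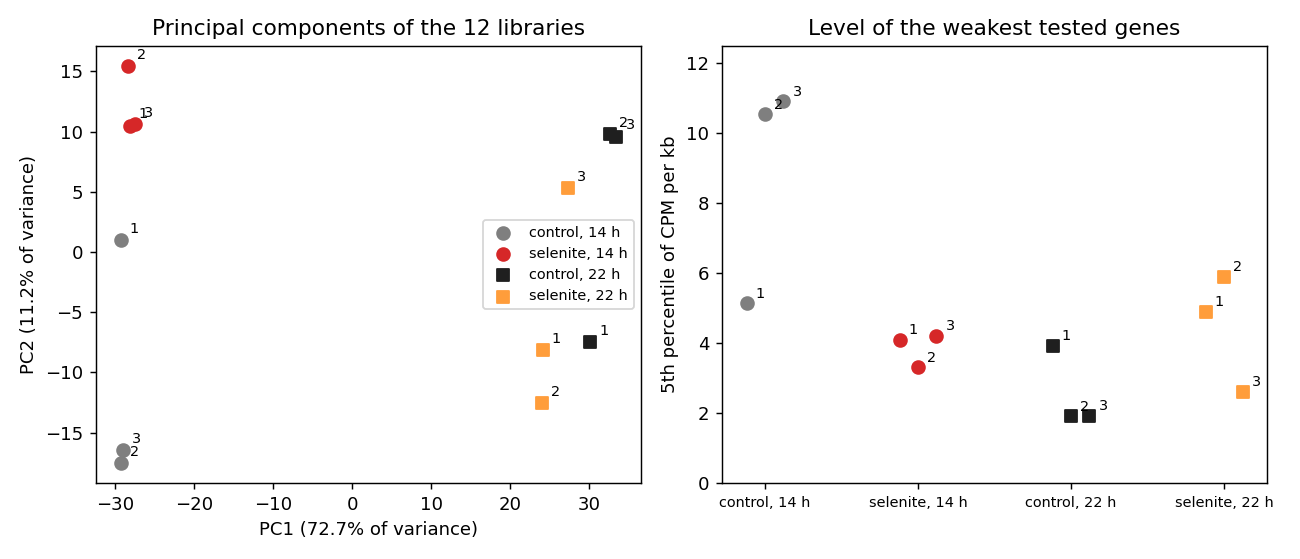
Left, the first and second principal components of log2 CPM for the 12 libraries, each point 1 library with its replicate number. Right, the 5th percentile of CPM per kb in each library; replicates 2 and 3 of control at 14 h lie at 10.5 and 10.9, above the other 10 libraries, whose highest value is 5.90.

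The first question was how selenite changed the transcriptome at 14 h. With selenite 15 of 18 fatty acid and phospholipid genes, 29 of 54 ribosomal protein genes and all 8 F0F1 ATP synthase genes rose, while 14 of 49 sugar phosphotransferase genes fell and 34 did not pass. No gene list was called at 14 h with an estimated correlation (lowest adjusted p = 0.346). Median log2 fold changes were 0.33 in the 176 most strongly counted genes (102 rose) and 0.258 in the 385 next in level (190 rose). The ribosomal protein median of 0.29 lay between these, so that rise was not separated from the trend with abundance. The sugar phosphotransferase median of -0.58 lay between -0.775 in the 405 most weakly counted genes and -0.296 in the 607 next. The fatty acid (0.51) and ATP synthase (0.46) medians lay above 0.33. LIU_RS01585, a methionine sulfoxide reductase of the MsrA type that repairs oxidised methionine, rose from 515 ± 11.2 to 1157 ± 203 CPM (SD, n = 3), and msrB, which acts on the other stereoisomer, rose from 2352 ± 108 to 4516 ± 308 CPM. Of 2242 genes tested with edgeR, 474 rose and 424 fell at adjusted p under 0.05. The falls depended on single libraries more than the rises, with 414 rises and 184 falls without replicate 2 of control, 324 and 210 without replicate 3 of control, 468 and 191 without replicate 2 of selenite, and 509 and 594 without replicate 1 of control. Only 14 of the rises and 155 of the falls were at least 2-fold.

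Among genes with an annotated product, at least 10 CPM and all 3 libraries of one group above the other, the largest rise was in LIU_RS11650, a transporter of the major facilitator superfamily at 2464513 to 2465700, with a log2 fold change of 1.73 ± 0.20 (SE) and an edgeR adjusted p of 1.4e-05. Next came the short-chain dehydrogenase LIU_RS04860 (1030960 to 1031610; 1.21 ± 0.12) and LIU_RS01585 (342544 to 343077; 1.17 ± 0.11). LIU_RS12915, a 3-deoxy-7-phosphoheptulonate synthase of aromatic amino acid synthesis, rose by 1.15 ± 0.12 and the aldo/keto reductase LIU_RS03670 by 1.09 ± 0.12. The proline synthesis gene proC rose by 1.09 ± 0.11, fabI (enoyl-ACP reductase) by 1.06 ± 0.12 and mscL, a mechanosensitive channel, by 1.01 ± 0.12 on the log2 scale. That all 3 selenite libraries lay above all 3 controls in each of these genes was a condition of the choice.

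In the fatty acid and phospholipid list 15 of 18 measured genes rose and none fell, with a median log2 fold change of 0.51 (camera adjusted p = 1.54e-05). The holo-ACP synthase gene LIU_RS00340, which the matching left out of this list, fell (-0.66, edgeR adjusted p = 0.00066). For the list the result differed with the correlation used. The camera adjusted p of the list was 0.346 with an estimated correlation. A run of 9 neighbouring synthesis genes at 1213869 to 1221079 held fabD at 0.46, accB at 0.77 and the biotin carboxylase gene LIU_RS05775 at 0.83. Its first gene, the acyl carrier protein LIU_RS05745, did not pass at -0.18. Of 54 ribosomal protein genes 29 rose and 5 fell (median 0.29, camera adjusted p = 2.81e-05), among them rplE at 0.70 ± 0.09 and rplF at 0.65 ± 0.09. That adjusted p was 0.577 with an estimated correlation.

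All 8 genes of the F0F1 ATP synthase at 2345598 to 2352184 rose, by 0.46 to 0.73 on the log2 scale, with atpD, the catalytic beta subunit, at 0.64 ± 0.09. Of the 7 measured V-type ATP synthase genes, which code for a separate ion pump, 1 fell and 6 did not pass. The list of both had a median of 0.46 (camera adjusted p = 0.0447), with an adjusted p of 0.577 with an estimated correlation. Thiol and peroxide defence had 7 rises and 2 falls among 19 genes (median 0.20, adjusted p = 0.027). Thioredoxin reductase trxB rose by 0.46 ± 0.09, while thioredoxin trxA (-0.11), gor, glutathione reductase (-0.11), and superoxide dismutase LIU_RS05585 (0.05) did not pass. A second MsrA gene, LIU_RS02710, fell (log2 fold change -1.55). Among cysteine, methionine and sulfur genes 4 of 17 rose and none fell (median 0.20, adjusted p = 0.0294). The methionine adenosyltransferase LIU_RS02500 rose by 0.88 ± 0.12 and the S-ribosylhomocysteine lyase LIU_RS13050 by 0.63 ± 0.09. For both lists the adjusted p was 0.577 with an estimated correlation.

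Aminoacyl-tRNA synthetases had 10 rises and 1 fall among 21 genes (median 0.21, camera adjusted p = 0.027), led by glutamate--tRNA ligase LIU_RS02010 at 0.82 ± 0.10 and lysS at 0.74 ± 0.11. Glycolysis and pyruvate had 10 rises and 1 fall among 22 (median 0.14, adjusted p = 0.0421; the median was -0.01 with total-count scaling), with gpmA, phosphoglycerate mutase, at 0.99 ± 0.12 and the L-lactate dehydrogenase LIU_RS02290 at 0.76 ± 0.09. The other L-lactate dehydrogenase, LIU_RS08060, did not pass at -0.08. In the phosphotransferase sugar uptake list 14 of 49 genes fell and 1 rose (median -0.58, adjusted p = 0.00682). Its members were weakly counted, with a median of 16.5 CPM, and with replicate 1 as the only control the median was -0.12. LIU_RS00010 fell from 165 ± 28.5 to 64.2 ± 12.8 CPM. In phosphate uptake 3 of 7 genes fell (median -0.31, adjusted p = 0.0421), with pstC at -0.64 ± 0.14. For each of these 4 lists the adjusted p was 0.577 with an estimated correlation. Of the 9 lists called at 14 h, only fatty acids were called over genes of at least 64 CPM alone, and only fatty acids, ribosomal proteins and phosphate uptake with background subtracted.

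The other lists were not called at 14 h. Chaperones and proteases had 7 rises and 1 fall among 18 genes, with groL (-0.05) and dnaK (-0.09) not passing and the Gls24 family stress protein gene LIU_RS08600 at 0.78 ± 0.09. DNA repair and SOS had 6 rises and 1 fall among 31, with lexA at 0.56 ± 0.09 and recA at 0.33 ± 0.09 (-0.064 with loess offsets). Candidate selenite reductases had 3 rises and 1 fall among 7. The NAD(P)H-dependent oxidoreductase LIU_RS10285 rose by 0.70 ± 0.09 and the nitroreductase LIU_RS07340 by 0.47 ± 0.10. Metal and metalloid homeostasis had 3 rises and 5 falls among 23. The P-type metal pump LIU_RS07195 rose by 0.82 ± 0.09, and the cadmium transporter LIU_RS14100 fell (-0.70). The arginine list had 1 rise, arcA at 0.68 ± 0.12 (arginine deiminase), and 1 fall, argH, among 6. Rises and falls were 7 and 4 of 28 in purine and pyrimidine synthesis, with nrdG at 0.93, 5 and 3 of 24 in cell wall, 7 and 10 of 43 in oligopeptide and amino acid uptake, 2 and 1 of 7 in glycerol, and 0 and 3 of 17 in prophage and transposon. The median and test of the arginine list and of purine and pyrimidine synthesis differed in sign, with medians of -0.04 and -0.03 and upward tests (adjusted p = 0.832 and 0.398).

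Adjusted over the list alone, 7 lists at 14 h gave other counts. They were 31 rises and 5 falls for ribosomal proteins, 10 and 2 for aminoacyl-tRNA synthetases, 10 and 2 for glycolysis, and 1 and 11 for sugar uptake. For cysteine, methionine and sulfur they were 3 and 0, for DNA repair 5 and 1, and for cell wall 2 and 1.

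The largest falls at 14 h under the same conditions were in weakly counted genes. They were LIU_RS07975, a helix-turn-helix protein (-2.11), ulaG, L-ascorbate 6-phosphate lactonase (-1.90), the competence gene LIU_RS07170 (-1.89) and trpD of tryptophan synthesis (-1.84). LIU_RS11755 (-1.81), LIU_RS08005 (-1.75), LIU_RS12225 (-1.74) and LIU_RS12945 (-1.67) followed. LIU_RS07975 went from 11.9 ± 4.92 to 2.72 ± 1.14 CPM. With replicate 1, the control library with the lower level of weak genes, as the only control, the fall was smaller in all 8. It was -1.29 for LIU_RS07975, -1.12 for LIU_RS08005, -0.62 for ulaG and -0.54 for trpD, as genes picked for the largest falls over all 3 controls may give. The 8 largest rises kept more of their size in that fit, at 0.85 to 1.39 against 1.01 to 1.73 with all 3 controls. Lists called fell from 9 to 5 without replicate 2 of control, where synthetases, ATP synthase, the sulfur list and glycolysis were not called. Median log2 fold changes ran from -0.775 in the 405 genes below 16 CPM to 0.33 in the 176 most strongly counted genes, and the rank correlation with abundance across genes was 0.647. Total-count scaling shifted the median by -0.15 and gave 299 rises and 643 falls. One fit of all 12 libraries shifted it by 0.17 and gave 672 and 236.

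**Figure D2:**
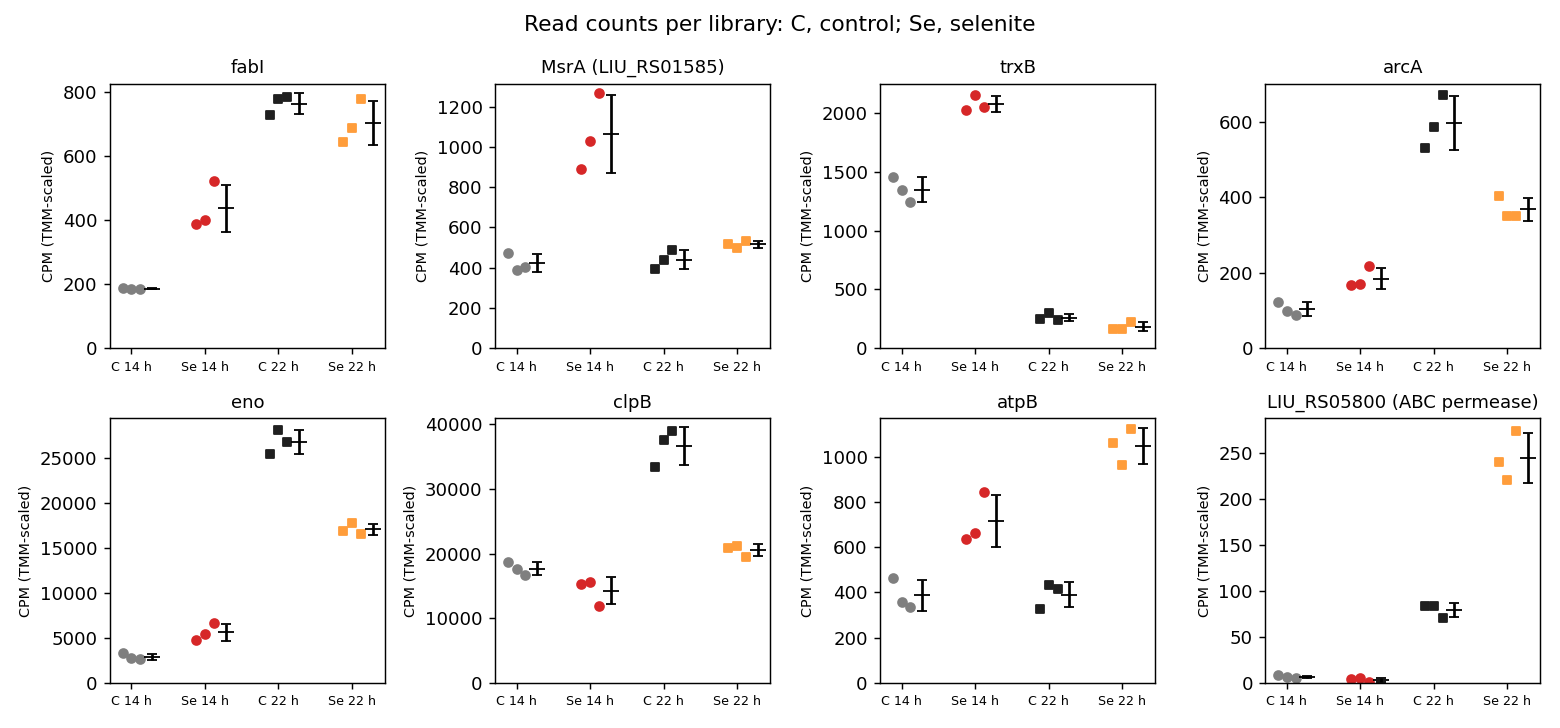
TMM-scaled CPM of 8 genes in each library (points), with mean and SD (n = 3) to the right of each group, on linear axes from 0. fabI, LIU_RS01585 and trxB were higher with selenite at 14 h, and atpB and LIU_RS05800 were higher with selenite at 22 h, where eno, clpB and arcA were lower.

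At 22 h 7 of 8 F0F1 ATP synthase genes rose with selenite, and 11 of 18 chaperone and protease genes, 12 of 21 glycolysis and pyruvate genes and 26 of 54 ribosomal protein genes fell. The medians of these last 3 lists were above 0 with total-count scaling, and no list was called with an estimated correlation (lowest adjusted p = 0.753). Median log2 fold changes were -0.335 in the 184 most strongly counted genes (131 fell) and -0.179 in the 316 next in level (156 fell). The list medians were -0.32 for chaperones, -0.23 for ribosomal proteins and -0.20 for glycolysis. The falls of these 3 lists were not separated from the trend with abundance. The disaggregase gene clpB fell from 31693 ± 2247 to 17769.8 ± 920.2 CPM (SD, n = 3), and eno, enolase, fell from 23153 ± 808 to 14751 ± 598 CPM. In contrast atpB, the F0F1 subunit A and the first gene of its run, rose from 338 ± 44.5 to 909 ± 65 CPM. Of 2167 genes tested with edgeR, 402 rose and 499 fell, of which 54 rises and 21 falls were at least 2-fold. Total-count scaling shifted the median log2 fold change by 0.32 and gave 877 rises and 166 falls.

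Chaperones and proteases had 11 falls and 2 rises among 18 genes (median -0.32, camera adjusted p = 0.000531). Beside clpB at -0.83 ± 0.06, the falls included dnaJ at -0.82 ± 0.06, groL at -0.58 ± 0.05 and dnaK at -0.55 ± 0.05. Ribosomal proteins had 26 falls and 2 rises among 54 (median -0.23, adjusted p = 0.000263), with rpsB at -1.18 ± 0.06 and rplU at -0.82 ± 0.06. Glycolysis and pyruvate had 12 falls and 2 rises among 21 (median -0.20, adjusted p = 0.0433). Beside eno at -0.65 ± 0.05, the glyceraldehyde-3-phosphate dehydrogenase LIU_RS11145 fell (-0.49 ± 0.05), though its value was 0.042 with loess offsets. Aminoacyl-tRNA synthetases had 11 falls and 3 rises among 21 (median -0.20, adjusted p = 0.048), with LIU_RS02560, leucine--tRNA ligase, at -0.55 ± 0.07. These 4 medians were above 0 with total-count scaling, at 0.01, 0.10, 0.13 and 0.12 in this order. With loess offsets those of glycolysis and synthetases were 0.04 and 0.04. With an estimated correlation the adjusted p was 0.753 for each.

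The ATP synthase list had 9 rises and 4 falls among 15 genes (median 0.48, camera adjusted p = 0.0433), and its adjusted p was 0.753 with an estimated correlation. Along the F0F1 genes, in the direction of transcription, the log2 fold change went from 1.43 ± 0.09 at atpB and 0.94 at atpE to 0.30 at atpD and -0.48 at the last gene, LIU_RS11035. A decline at 22 h was also seen along 40 runs of neighbouring genes outside the lists, with a mean slope of -0.131 log2 units per kb. Of the V-type genes 2 rose and 3 fell. Lists called fell from 5 to 2 without replicate 2 of control at 22 h and to 3 without replicate 1 of selenite, and the ATP synthase list was not called in either case. Over genes of at least 64 CPM alone no list was called at 22 h, and with background subtracted glycolysis and synthetases were not called. The phosphate uptake list, with 4 rises and 1 fall among 7 genes, was not called (adjusted p = 0.262). Its substrate-binding gene LIU_RS10910 rose by 1.10 ± 0.18 and pstC by 1.06 ± 0.13. The fatty acid list had 7 rises and 5 falls among 18 (adjusted p = 0.695), with fabD at 1.12 ± 0.10 and pgsA, phosphatidylglycerophosphate synthase, at -0.81 ± 0.07.

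Candidate selenite reductases had 4 falls among 7 genes and were not called (adjusted p = 0.306; median -0.26, or 0.06 with total-count scaling), with LIU_RS10285 at -0.59 ± 0.07 and LIU_RS07340 at -0.56 ± 0.10. In thiol and peroxide defence 8 of 19 genes fell and 4 rose (adjusted p = 0.589). Falls were -0.52 ± 0.12 for trxB, -0.39 ± 0.06 for trxA and -0.40 ± 0.08 for gor, of which all 3 lost their call with total-count scaling, while superoxide dismutase LIU_RS05585 rose by 0.28 ± 0.06. The arginine list had 2 rises and 4 falls among 6 genes and was not called (adjusted p = 0.262). Its arginine deiminase gene arcA at -0.69 ± 0.09, arcC at -1.03, the ornithine carbamoyltransferase gene argF at -1.18 ± 0.11 and LIU_RS03860 at -0.47 fell. In the same list argH rose by 0.78 and LIU_RS05170 by 0.76. In cysteine, methionine and sulfur 6 genes rose and 5 fell of 17, with the cysteine desulfurase LIU_RS11890 at 1.01 ± 0.11 and sufC at 0.76 ± 0.07. DNA repair and SOS had 12 rises and 9 falls of 31, with ligA at 0.85 ± 0.08 and recA at -0.67 ± 0.07. Rises and falls were 8 and 5 of 23 in cell wall, 4 and 2 of 7 in glycerol, 2 and 6 of 23 in metals, 8 and 8 of 43 in peptide and amino acid uptake, and 9 and 6 of 47 in sugar uptake. They were 10 and 6 of 28 in purine and pyrimidine synthesis and 2 and 2 of 15 in prophage and transposon, where the holin gene LIU_RS08820 fell from 8.3 ± 3.72 CPM to 0.782 ± 0.326 CPM, with a mean below the level of 3 counts (0.947 to 1.059 CPM with selenite at 22 h). Median and mean differed in sign for the sulfur, DNA repair, prophage and thiol lists, none of them called.

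Among genes of at least 10 CPM with an annotated product and all 3 libraries of one group above the other, the largest falls at 22 h were the holo-ACP synthase LIU_RS00340 (85537 to 85887; -1.78 ± 0.25), the regulator LIU_RS04465 (-1.49 ± 0.23) and LIU_RS09405 (-1.28 ± 0.10), a phosphotransferase gene. LIU_RS09405 at 1991811 to 1993742 lies next to pfkB, 1-phosphofructokinase, which fell (-1.20 ± 0.14). LIU_RS00330, a PemK/MazF family toxin (-1.21 ± 0.37; not called with total-count scaling), rpsB, argF and the Spx family regulator LIU_RS13075 (-1.09 ± 0.12) completed the 8. The largest rises were LIU_RS03540 (1.73 ± 0.38), the amino acid transporter permease LIU_RS05800 (1223790 to 1224479; 1.63 ± 0.10), LIU_RS03545 (1.61 ± 0.32) and LIU_RS02685 (1.51 ± 0.28). With atpB, def (1.42 ± 0.41), the Cas9 gene LIU_RS02765 (1.32 ± 0.21) and the stress membrane protein gene LIU_RS05125 (1.30 ± 0.11) followed. LIU_RS05800 rose from 68.4 ± 6.38 to 212 ± 22.4 CPM (edgeR adjusted p = 2.26e-09). LIU_RS03540 stood at only 3.95 ± 0.906 and 13.1 ± 1.63 CPM. Adjusted over the list alone, counts of rises and falls at 22 h became 3 and 13 for aminoacyl-tRNA synthetases, 2 and 12 for chaperones and 8 and 5 for fatty acids. They became 1 and 4 for candidate selenite reductases, 7 and 5 for the sulfur list, 1 and 6 for metals and 11 and 6 for purines and pyrimidines.

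**Figure D3:**
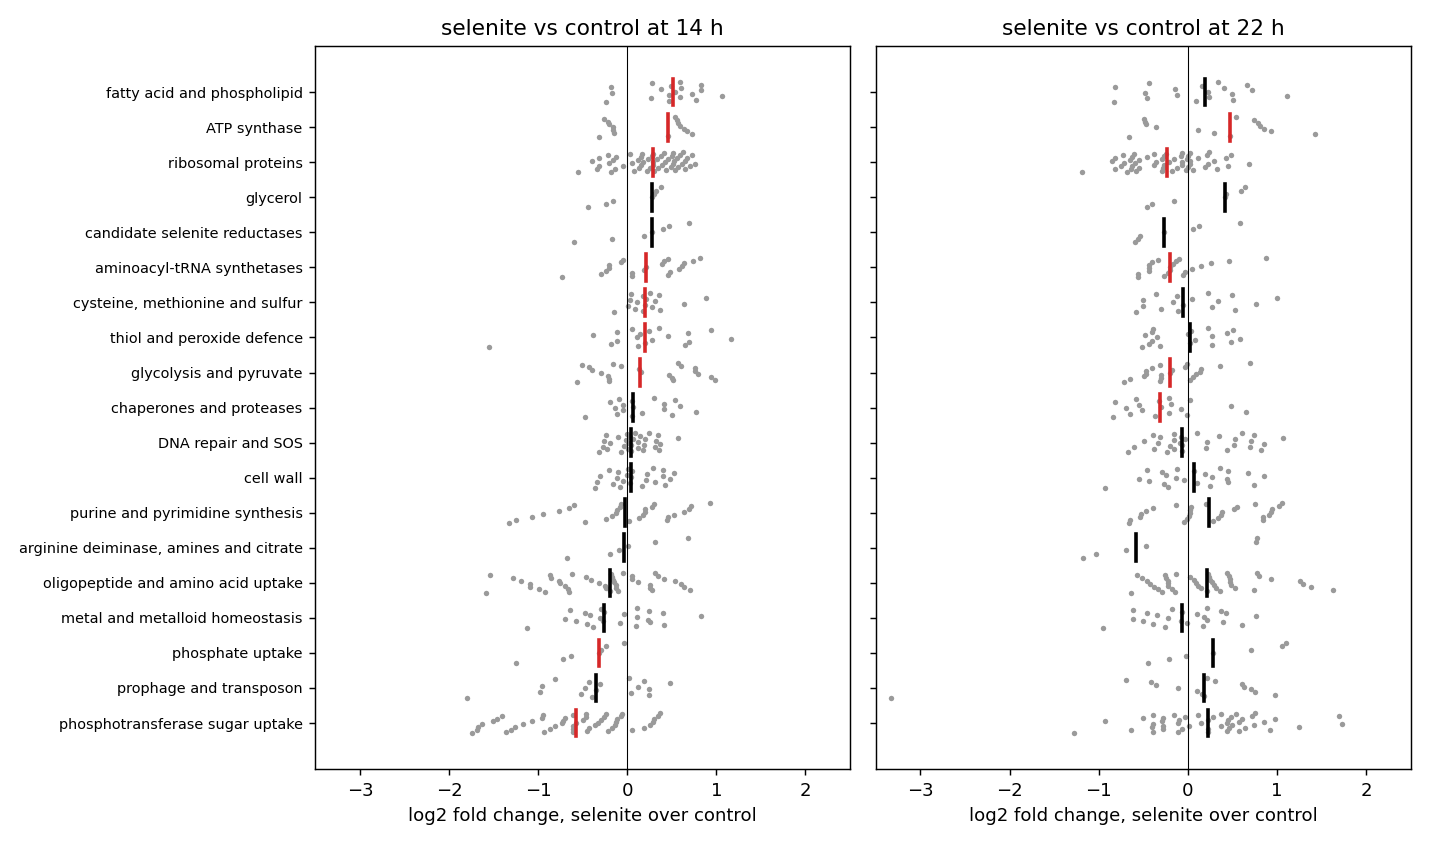
Log2 fold change, selenite over control, of each member of the 19 gene lists (grey points) with the list median (bar), at 14 h and 22 h. Red bars mark lists with a camera adjusted p under 0.05 at a preset correlation of 0.01, 9 at 14 h and 5 at 22 h; with an estimated correlation there were 0 at either time, and at 22 h the 4 red medians below 0 lay above 0 with total-count scaling.

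The selenite responses at the 2 times differed in 849 of 2282 genes by the edgeR interaction test, 284 toward a higher and 565 toward a lower response at 22 h. Ribosomal protein genes had the smallest camera adjusted p (1.26e-09), with 36 of 54 lower, none higher and a median of -0.68, and chaperones and proteases had 15 of 18 lower and none higher. With an estimated correlation the adjusted p was 0.534 for both. The median interaction was -0.787 in the 183 most strongly counted genes and -0.555 in the 365 next in level. The shifts of these lists, with -0.67 for chaperones, were not separated from the trend with abundance. The enolase gene eno went from 0.80 at 14 h to -0.65 at 22 h. In the opposite direction LIU_RS05800 went from -1.09, which did not pass at 14 h, to 1.63, an interaction of 2.54 ± 0.37 (adjusted p = 2.96e-06). The arginine deiminase gene arcA went from 0.68 to -0.69, an interaction of -1.54 ± 0.19 (adjusted p = 2.5e-07).

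Among genes of at least 10 CPM with an annotated product whose selenite minus control differences did not overlap between the times, the largest interactions toward a lower response were LIU_RS11650 (-1.96 ± 0.27), pfkB (-1.86 ± 0.20), the divalent metal transporter LIU_RS10795 (-1.78 ± 0.15), LIU_RS04860 (-1.71 ± 0.18) and LIU_RS09405 (-1.70 ± 0.18). Toward a higher response they were LIU_RS11520 (2.61 ± 0.61), LIU_RS05800, the Cas9 gene LIU_RS15535 (2.40 ± 0.59), the phosphotransferase gene LIU_RS11680 (2.37 ± 0.54) and LIU_RS03540 (2.17 ± 0.45). Lists shifted downward were chaperones (-0.67, but 0.20 with loess offsets), aminoacyl-tRNA synthetases (-0.52), glycolysis (-0.52), fatty acids (-0.43) and thiol defence (-0.34), and upward phosphotransferase sugar uptake (0.78) and phosphate uptake (0.62). For all 8 called lists, ribosomal proteins included, the adjusted p was 0.534 with an estimated correlation. With total-count scaling, which shifted the median of all genes by 0.64, the interaction gave 1127 higher and 191 lower (334 and 362 with loess offsets), and the medians of aminoacyl-tRNA synthetases, glycolysis, fatty acids and thiol defence lay above 0. The interaction median of ribosomal proteins was -0.043 with total-count scaling and -0.17 with loess offsets, and that of sugar uptake was 0.22 with loess offsets. The call of phosphate uptake was lost without replicate 1 of control at 14 h. Over genes of at least 64 CPM alone only ribosomal proteins were called, and with background subtracted fatty acids, thiol defence and sugar uptake were not. Adjusted over the list alone, higher and lower counts were 0 and 38 for ribosomal proteins, 2 and 15 for synthetases, 2 and 8 for fatty acids and 9 and 3 for sugar uptake.

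Of 2149 genes tested at both times, 387 were called at both. With selenite 110 rose at both times, where independent lists would share 88.2, and 70 fell at both (94.5 if independent). Another 172 rose at 14 h and fell at 22 h (110 if independent), and 35 did the reverse (75.9 if independent). Which of the last 2 counts was larger depended on scaling. With total-count scaling 40 rose and then fell and 168 did the reverse (22.96 and 254.9 if independent). The first thus stayed above and the second below the count if independent. With loess offsets 74 and 61 did (68.3 and 60.6 if independent), so that little of either difference was left. The fold changes also followed abundance in opposite directions, with rank correlations of 0.647 at 14 h and -0.386 at 22 h. Across genes, which are not independent replicates, the log2 fold changes at the 2 times had Pearson's r of -0.149 and Spearman's rho of -0.156. With total-count scaling r was -0.145, and with loess offsets 0.063.

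**Figure D4:**
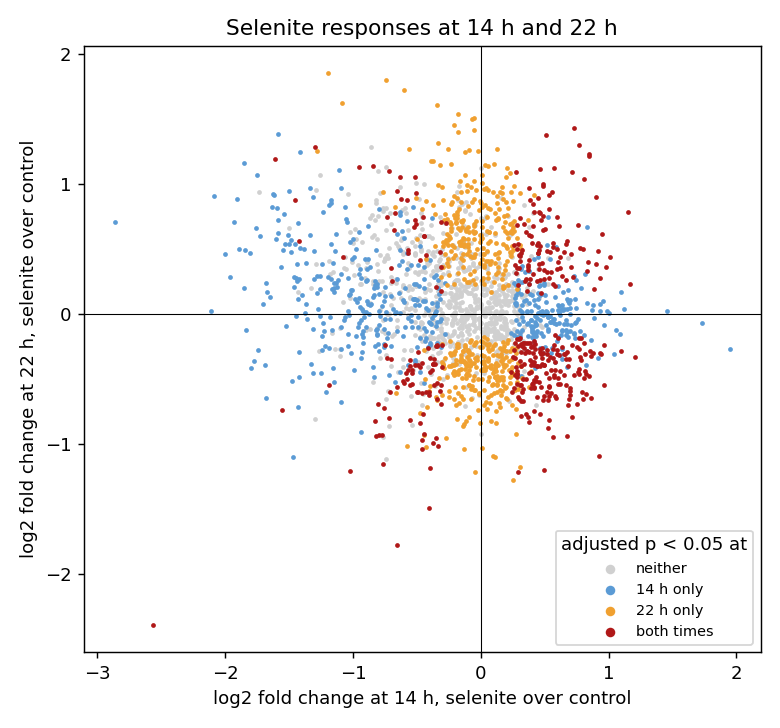
Log2 fold change of selenite over control at 14 h (horizontal) and 22 h (vertical), each point 1 of 2149 genes, coloured by the times at which edgeR gave an adjusted p under 0.05. The 387 genes called at both times hold 172 that rose at 14 h and fell at 22 h, against 110 if independent (40 against 22.96 with total-count scaling). Over all genes r was -0.149 (0.063 with loess offsets).

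Between 14 h and 22 h in broth without selenite, transcripts of a mannose-type phosphotransferase run and of the chaperonin gene groL rose and those of a 3-gene run with a rhodanese-like gene fell. The mannose-type phosphotransferase gene LIU_RS05115 rose from 62.4 ± 9.65 to 8779.7 ± 1047 CPM, and groL rose from 4918 ± 147 to 33616 ± 1996 CPM (SD, n = 3). LIU_RS02890, an FAD-dependent oxidoreductase beside a rhodanese-like gene, fell from 2165 ± 165 to 14.7 ± 5.28 CPM. Of 2235 genes, 822 rose and 773 fell by edgeR. Total-count scaling shifted the median by -0.86 and gave 447 rises and 1411 falls, while 1 fit of all 12 libraries shifted it by -0.12 and loess offsets by 0.12.

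The largest rises were LIU_RS05115 (7.13 ± 0.13), LIU_RS05110 (5.71 ± 0.14) and manX (5.15 ± 0.12) of that run at 1083361 to 1086700, the L-lactate dehydrogenase LIU_RS08060 (5.29 ± 0.10) and the amino acid transporter gene LIU_RS05805 (4.52 ± 0.14). LIU_RS08060 reached 17495 ± 1098 CPM from 446 ± 56.2 CPM. Among genes of at least 10 CPM with an annotated product and separate libraries, the largest falls were the rhodanese-like gene LIU_RS02885, which fell to 0.763 ± 0.953 CPM, below the level of 3 counts (0.983 to 0.991 CPM in control at 22 h), from 129 ± 21 CPM, then LIU_RS02890 (-7.18 ± 0.15) and the metal-sensitive regulator LIU_RS02880, from 47.2 ± 4.27 to 1.19 ± 0.968 CPM, all at 610144 to 612540. The level of 3 counts is given on unscaled totals. TMM factors of control at 22 h were 0.716 to 0.794 in this comparison, which puts that level higher on the scale of these CPM. The 1.19 CPM of LIU_RS02880 was thus not above it either. LIU_RS13200 (-3.60 ± 0.16) and LIU_RS08505 (-3.49 ± 0.28) followed. dnaK rose by 1.86 ± 0.07 and arcA by 2.66 ± 0.11, while trxB (-2.25 ± 0.10), trxA (-1.61 ± 0.07) and gor (-1.33 ± 0.09) fell. Rises of 0.54 in LIU_RS02290 and 0.57 in superoxide dismutase LIU_RS05585 became -0.32 and -0.29 with total-count scaling and -0.63 and -0.38 with loess offsets.

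Camera called 4 lists upward: aminoacyl-tRNA synthetases (19 of 21 rose, median 1.21, adjusted p = 3.9e-05), chaperones (14 of 18, 1.51, 0.000606), glycolysis (15 of 21, 1.07, 0.00173) and ATP synthase (10 of 15, 0.72, 0.0174). The adjusted p was 0.703 with an estimated correlation for synthetases and glycolysis and 0.722 for the other lists. Over all genes the change over time in control also followed abundance (rank correlation of 0.454). Its median was 1.223 in the 180 most strongly counted genes and 0.92 in the 354 next in level. The synthetase and glycolysis medians lay between these and that of ATP synthase below both. Those rises were not separated from the trend with abundance, while the chaperone median lay above 1.223. The ATP synthase median was -0.14 with total-count scaling, and the list was not called with background subtracted. Over genes of at least 64 CPM alone only synthetases were called. The phosphotransferase list, with 17 rises and 6 falls of 47, had 16 and 4 when adjusted over the list alone, and its median of -0.18, mean of 0.57 and upward test (adjusted p = 0.397) differed in sign.

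In selenite cultures LIU_RS05115 of the same mannose-type run had the largest rise from 14 h to 22 h, and the thioredoxin reductase gene trxB fell further on the log2 scale than in control. LIU_RS05115 rose by 6.73 ± 0.16 and LIU_RS05800 from 3.4 ± 2.24 to 248 ± 41.1 CPM (SD, n = 3). trxB fell from 2061 ± 44.6 to 185 ± 47.7 CPM. Its change of -3.48 ± 0.14 compared with -2.25 in control, an interaction of -1.14 ± 0.18 (edgeR adjusted p = 6.92e-06). For trxA the change was -2.15 ± 0.13 and the interaction -0.45 ± 0.14 (adjusted p = 0.015), which was 0.20 with total-count scaling and 0.52 with loess offsets, and not called without replicate 2 or 3 of control at 22 h, 3 of selenite at 14 h, or 1 or 2 of selenite at 22 h.

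Of 2215 genes 732 rose and 793 fell. After LIU_RS05115 the largest rises were LIU_RS05800 (6.16 ± 0.23), LIU_RS05805 (5.97 ± 0.18), LIU_RS05110 (5.90 ± 0.15) and manX (5.78 ± 0.15). The largest falls under the same conditions were LIU_RS02890 (-6.02 ± 0.36), LIU_RS02885, from 72.9 ± 16.7 to 1.31 ± 1.69 CPM, the Y-family DNA polymerase LIU_RS12920 (-4.36 ± 0.14), the dioxygenase LIU_RS06115 (-4.16 ± 0.16) and the cysteine synthase family gene LIU_RS13040 (-4.12 ± 0.16). groL rose by 1.98 ± 0.13, dnaK by 1.15 ± 0.12 and arcA by 1.03 ± 0.13, and gor fell (-1.88 ± 0.12). Total-count scaling shifted the median by -0.12.

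Over time with selenite 7 lists were called upward. They were aminoacyl-tRNA synthetases (14 of 21 genes rose), ATP synthase (13 of 15), chaperones (12 of 18), phosphotransferase sugar uptake (23 of 48), phosphate uptake (6 of 7), peptide and amino acid uptake (20 of 43) and the arginine list (5 of 6). Ribosomal proteins (32 of 54 fell, median -0.66) and candidate selenite reductases (5 of 7 fell, median -1.53) were called downward. The reductases that fell included LIU_RS07340 at -2.89 and LIU_RS07350 at -2.82, both nitroreductases, while the azoreductase LIU_RS04000 rose by 1.68. With an estimated correlation the adjusted p of these 9 lists ran from 0.438 to 0.71. Without replicate 3 of selenite at 22 h the called lists were 5, and the arginine, reductase, chaperone and peptide uptake lists were not called. Over genes of at least 64 CPM alone only synthetases, ATP synthase and sugar uptake of the 9 were called, and with background subtracted the arginine, reductase, peptide uptake and ribosomal protein lists were not. Adjusted over the list alone, rises and falls were 14 and 0 for ATP synthase, 20 and 6 for peptide uptake, 13 and 33 for ribosomal proteins and 7 and 11 for thiol defence.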

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

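The tests of library totals, of 1 control library against the other 2, and of shuffled gene order were chosen after the results were seen, as were the fits with background subtracted, with loess offsets, with strongly counted genes alone and with replicate 1 as the only control.

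By the edgeR interaction test, whose values followed abundance (rank correlation of -0.677), the selenite response differed between 14 h and 22 h in 849 genes. Among 100 splits of the libraries the highest other gave 729 and only 1, the real one, reached this count. The split with 729 exchanged selenite and control at 22 h. For gene lists 8 were called, 15 of 100 splits gave as many, and the highest other gave 11. The splits exchanged selenite and control within each time, so that they stand for no selenite response at all. They do not stand for an equal response at both times, so they do not decide whether the responses differ by chance.

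The named genes whose response was lower at 22 h by this test are given with the interaction on the log2 scale. They were LIU_RS11650 -1.96, pfkB -1.86, LIU_RS10795 -1.78, LIU_RS04860 -1.71, LIU_RS09405 -1.70, argF -1.65, eno -1.61, LIU_RS07195 -1.61, LIU_RS03670 -1.54, arcA -1.54, pgsA -1.51, guaA -1.51, LIU_RS10285 -1.46, LIU_RS02010 -1.42, msrB -1.42, proC -1.40, LIU_RS13075 -1.37, fabI -1.35 and LIU_RS02500 -1.34. Smaller values were LIU_RS00340 -1.28, LIU_RS08600 -1.27, LIU_RS11145 -1.27, LIU_RS04465 -1.25, LIU_RS07340 -1.19, recA -1.16, trxB -1.14, gpmA -1.12, LIU_RS01585 -1.10, ptsP -1.10, LIU_RS00075 -1.09, nrdG -1.08, lexA -1.07, rplU -1.07, LIU_RS00090 -1.04, LIU_RS02290 -0.95, rpsB -0.95, LIU_RS13050 -0.91 and dhaL -0.91. The smallest were LIU_RS05775 -0.91, rplF -0.89, copB -0.88, dnaJ -0.87, lysS -0.86, rplE -0.86, LIU_RS01460 -0.83, LIU_RS08405 -0.76, mscL -0.73, groL -0.70, LIU_RS02560 -0.64, LIU_RS03795 -0.63, dnaK -0.61, nrdD -0.60, clpB -0.53, LIU_RS10600 -0.52, atpD -0.51, gor -0.45 and trxA -0.45. Of these, dnaK, gor and trxA turned positive with total-count scaling (0.016, 0.18 and 0.20), and groL, dnaK and trxA with loess offsets (0.35, 0.43 and 0.52).

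Named genes with a higher response at 22 h were fabD 0.49, atpB 0.54, ligA 0.57, LIU_RS11890 0.84, glpK 0.87, LIU_RS01995 1.11, LIU_RS00010 1.15, LIU_RS05100 1.21, argH 1.28, def 1.30, LIU_RS02685 1.39, LIU_RS08960 1.41, LIU_RS02765 1.48, LIU_RS05805 1.53, pstC 1.53, LIU_RS12945 1.65, LIU_RS10910 1.65, LIU_RS03545 1.80, LIU_RS07975 1.95, LIU_RS11755 2.09, trpD 2.14, LIU_RS03540 2.17, LIU_RS07170 2.19, LIU_RS11680 2.37, LIU_RS15535 2.40, LIU_RS05800 2.54, ulaG 2.59, LIU_RS11520 2.61 and LIU_RS08005 2.64. Of these, LIU_RS00010, LIU_RS08960, LIU_RS12945, LIU_RS07975, LIU_RS11755, trpD, LIU_RS07170, LIU_RS11680, ulaG and LIU_RS08005 were not called at 22 h. Their interactions rest mainly on falls at 14 h. With replicate 1 as the only control some of those falls were smaller, at -0.62 against -1.90 for ulaG and -0.54 against -1.84 for trpD.

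Among lists, the median interaction was -0.52 for aminoacyl-tRNA synthetases, -0.67 for chaperones and proteases, -0.43 for fatty acid and phospholipid, -0.52 for glycolysis and pyruvate, -0.68 for ribosomal proteins and -0.34 for thiol and peroxide defence. It was 0.62 for phosphate uptake and 0.78 for phosphotransferase sugar uptake. None of these lists was called with an estimated correlation (adjusted p = 0.534 for each). With total-count scaling the medians of synthetases, glycolysis, fatty acids and thiol defence lay above 0, and that of chaperones was 0.20 with loess offsets. The shifts of synthetases, chaperones, glycolysis, ribosomal proteins, thiol defence and sugar uptake were not separated from the trend with abundance.

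For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. Genes called were 898 at 14 h, 901 at 22 h, 1595 over time in control and 1525 over time with selenite, and the highest other split gave 0 in each, so that 1 split reached each count. Lists called were 9 at 14 h (highest other 8), 5 at 22 h (highest other 4), 4 over time in control (highest other 6, with 5 splits reaching the count) and 9 over time with selenite (highest other 4). With an estimated correlation no list was called in any of these 4 comparisons.

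The first pattern weighed was a trend with abundance, in which weakly counted genes were lower with selenite at 14 h and higher at 22 h. Totals at 14 h were close, 2858573 to 3029521 in control and 2923616 to 3031750 with selenite. Thinning to the smallest total left the rank correlation at 14 h at 0.647, but could move little and so does not decide. Without the 10 most abundant genes it was 0.648. That step acts on the scaling, and a shift common to all genes cannot change a rank correlation, so it does not decide either. The correlation was 0.646 with median-ratio factors and 0.649 with total-count scaling. Even background reads stay open, since subtraction left 0.425 at 14 h and -0.255 at 22 h. A difference between libraries that selenite does not set also stays open, because 1 control library against the other 2 gave up to 0.51 at 14 h and, at 22 h, where the selenite trend was -0.386, replicate 1 of control gave -0.435. Against the others of their group at 22 h, replicates 2 and 3 of selenite gave -0.392 and 0.415. A response to selenite itself is the biological alternative and was not separated from these.

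The second pattern was that genes with a count of 0 in all 12 libraries lay in long runs, 288 of 453 in 8 runs of at least 10 genes, the longest of 70. Of these runs 3, with 29, 18 and 12 genes, held only rRNA, tRNA or transposase genes, and the tests below left these classes out. Low depth is argued against, as 20 genes had 1 to 10 counts against 302 at 0. Chance placement is too, as 0 of 10000 shuffles reached the longest run, which held 68 genes in this test. Taking these classes out of the gene order joined genes at 0 on either side of them, so this is not the run of 70. Reads shared with a second copy stay open, with 23.81% of 63 neighbouring product pairs found elsewhere. A listed sequence that holds segments this culture lacks was not tested, and no group of the design bears on it.

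The third pattern was a smaller change from 14 h to 22 h with selenite than without, with a slope of 0.877 across 2196 genes (0.816 to 0.89 with each library left out). The slope was 0.948 with background subtracted and 0.932 over genes of at least 64 CPM. Background reads and weakly counted genes each moved it toward 1 and stay open, and a response to selenite was not separated from them.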

How the results depend on the processing

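Loess offsets, background subtraction, strongly counted genes alone, the fits without replicate 1 of both control groups or with replicate 1 as the only control, and lists with each replicate left out were chosen after the data were seen. Of 172 results for named genes, 172 kept direction and side of the threshold with median-ratio factors, 171 without a count filter, 148 with total-count scaling and 140 with loess offsets, and 169 of 170 with DESeq2. With each replicate left out 1116 of 1146 did, and 33 of 59 with replicate 1 as the only control at 14 h. The cause was not tested for any change below, except that a stricter threshold gives fewer calls by construction. At 3 counts per library, levels under about 1.06 CPM on unscaled totals could not be measured. On the TMM scale of a comparison this limit moves with the factor of each library.

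The stricter threshold gave 59 genes at 14 h, 58 at 22 h, 909 over time in control, 745 over time with selenite and 220 for the interaction. Replicate 1 as the only control, assumed to vary like the selenite libraries, gave 209 genes at 14 h and 5 lists. Strongly counted genes alone gave 1039 genes over time in control and 975 with selenite, and total-count scaling 1318 for the interaction. With each replicate left out the counts were 534 to 1103 at 14 h, 774 to 931 at 22 h, 1474 to 1660 over time in control, 1410 to 1562 with selenite and 714 to 1047 for the interaction.

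Lists called with an estimated correlation were 0 in all 5 comparisons. Strongly counted genes alone gave 1 list at 14 h, 0 at 22 h, 1 over time in control, 4 with selenite and 1 for the interaction. Background subtraction gave 3 at 14 h, 3 at 22 h, 5 over time with selenite and 5 for the interaction. With each replicate left out they were 5 to 9 at 14 h, 2 to 5 at 22 h, 4 to 6 over time in control, 5 to 10 with selenite and 7 to 8 for the interaction.

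Log2 values that changed sign with total-count scaling were LIU_RS02290 (0.29) and LIU_RS08060 (0.13) at 22 h, LIU_RS02290 (-0.32) and LIU_RS05585 (-0.29) over time in control, and gor (0.18), dnaK (0.016), trxA (0.20) and LIU_RS08060 (0.35) in the interaction. With loess offsets they were recA (-0.064) at 14 h, LIU_RS11145 (0.042), LIU_RS02290 (0.26) and LIU_RS08060 (0.28) at 22 h, LIU_RS02290 (-0.63) and LIU_RS05585 (-0.38) over time in control, and dnaK (0.43), trxA (0.52), groL (0.35) and LIU_RS08060 (0.56) in the interaction.

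Samples shared only a replicate number. Deviations of same-numbered libraries correlated from -0.586 to 0.327 over 12 pairs, and 1 of 12 correlated best with its own number. As deviations from means of 3 libraries, they do not decide whether equal numbers share a culture. The replicate block gave 863 genes at 14 h, 930 at 22 h, 1494 over time in control, 1447 with selenite and 790 for the interaction.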

Other observations

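The comparisons below were outside the report, and the genes in them were chosen after their values were seen; the predictions for the gradient along gene runs were written before its test was run.

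Over culture time, a pair of neighbouring sulfur amino acid genes fell in both media, while the gene beside them rose. The cysteine synthase family gene LIU_RS13040 changed by -3.26 in control and -4.12 with selenite on the log2 scale, and the cystathionine gamma-synthase gene LIU_RS13045 by -3.41 and -3.70. The S-ribosylhomocysteine lyase gene LIU_RS13050 changed by 1.59 and 0.58, and the sulfur list had 10 rises and 5 falls of 17 in control and 9 and 7 with selenite. The metal pump gene LIU_RS07195 changed over time by -2.09 in control and -3.79 with selenite, and the cadmium transporter gene LIU_RS14100 by -2.25 and -2.15.

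Of 7 measured candidate selenite reductase genes 3 rose with selenite at 14 h and fell at 22 h, while the list was called at neither time nor in the interaction (4 lower and 1 higher, adjusted p = 0.106). The nitroreductases LIU_RS07340 and LIU_RS07350 had log2 fold changes of 0.47 and 0.41 at 14 h and -0.56 and -0.53 at 22 h. The oxidoreductase LIU_RS10285 had 0.70 and -0.59.

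Genes with a count of 0 in all libraries filled segments such as 2908876 to 2972242 (70 genes, with sortase and bacteriocin genes) and 3038538 to 3072982 (42 genes, with heavy metal and cadmium pump genes).

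A hypothesis from the F0F1, V-type, fatty acid and phosphate gene runs is that the selenite difference at 22 h may decline along runs of neighbouring genes in general. It was tested in 40 other runs (183 genes, same strand, gaps of at most 50 bp, at least 4 tested genes), which hold no list member. The mean slope at 22 h was -0.131 log2 units per kb ± 0.027 (SE over runs), below 0 in 30 of 40 runs, with a sign-flip permutation p of 1e-05, the smallest these flips can give (adjusted p = 1.67e-05 over 5 comparisons, two-sided). At 14 h the slope was 0.078 ± 0.021, and 0.041 after removal of the trend with abundance (sign-flip permutation p = 0.0482). After removal of the trend with abundance 73.3% of the slope at 22 h was left, so that this trend stays open as part of it. Runs are from the same 12 libraries in which the pattern was noticed. The sign-flip p measures spread over runs and not over cultures, so it does not show that selenite cultures differ. Over time in control the slope in these runs was larger, at 0.339 ± 0.066.

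Within libraries, the mean slope of log2 CPM along these runs was 0.23 ± 0.016 in control and 0.306 ± 0.029 with selenite at 14 h, and 0.566 ± 0.032 and 0.436 ± 0.031 at 22 h (SD, n = 3). RNA decay, transcript ends and library preparation were not tested as sources of these slopes.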
